A study of Homo sapiens with 6 samples.

How the data were processed

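Total RNA was taken, per the labels' protocols, from cultures at 70% confluence with an RNeasy kit, and 40 ng of each sample was amplified into cDNA, fragmented and labelled with biotin with a NuGEN Ovation kit. The arrays were of a 1-colour Affymetrix human expression design, with 54675 probe sets per array. The deposited values were signal intensity values on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version and the scaling target are not given in the sources used here. The values showed that each array had been scaled to the same mean after trimming 2% of probe sets at each end. MAS5 subtracts mismatch-probe signal, so values near background run down to 0, and ratios of such values are unstable. No present or absent calls were used here. Replicates were deposited one array each and not pooled.

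Gene names were taken from GEO's annotation of the platform, and symbols were checked through Entrez identifiers against a RefSeq gene table of the assembly GRCh38.p14, which changed 0 of them. Of 54613 probe sets that are not controls, 41091 named 1 gene, 1801 named several and 11721 were unnamed here. Of those naming 1 gene, 41037 matched the gene table, and probe sets naming several genes or none were left unnamed. The 62 control probe sets were left out of the tests. Control probe sets for human RNA were examined separately, and those for 1 human gene are not reported here. No genome build is given for the array in the sources used here, so no coordinates are given, and the gene table was used only for names and for the order of neighbouring genes.

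The intensities were transformed to log2(signal + 16), which understates the change of dim genes, and no further normalization was applied, since MAS5 had already scaled the arrays. Probe sets were tested where their mean over the 6 arrays was at or above the 40th percentile, which corresponds to a signal of 5.62. The samples labelled Fry clone were compared with the parental samples with lmFit and eBayes of limma 3.58.1 in R 4.3.3, over all 6 arrays without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each gene was represented by its probe set with the highest mean among those naming 1 gene. Of 7235 genes with several tested probe sets, 487 had probe sets called in both directions. Standard errors are those of limma, and signals are given as mean and SD on the linear scale. A group was taken as not above background for a probe set where each of its 3 arrays read at or below the highest of the 27 unspiked bacterial control probe sets on that array, which lay between 2.5 and 4.9. Then the fold is given as a lower bound, the bright group's mean log2 signal against that control level or the probe set's own signal, whichever was higher. The median signal of all probe sets, 10.4 to 12.1 over the arrays, lay above that level. A higher floor would therefore give smaller folds.

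A list of 21 gene groups was fixed before the data were examined, as were the test, the filter, the alternatives and the rule for the genes named in the text. By that rule the text names the 12 largest rises and the 12 largest falls on log2(signal + 16) among genes that passed, whose groups did not overlap and whose higher group was at or above the median of tested probe sets. It also names up to 4 members with the smallest p in each list, and FRY and FRYL. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 21 lists, with camera at an estimated correlation and with fry as alternatives. The limit to genes with a mean signal of at least 100 in a group was added as an alternative after the data had been seen. Lists of melanocyte and neural crest genes, of 8 other lineages (hepatocyte, neuron, skeletal muscle, adipocyte, endothelial, intestinal, prostate, keratinocyte), of HLA class I and class II genes and of HOX genes were written after the leading genes had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

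Quality was checked. The 3'-to-5' signal ratio of the GAPDH control probe sets, a sign of RNA quality, was 1.36 to 1.39 on the parental arrays and 1.24 to 1.33 on the arrays labelled Fry clone, so every array of the second group lay below every parental array. That of the beta-actin control probe sets was 2.59 to 3.00 and 2.45 to 2.65, with overlapping groups. The median SD between arrays of a group was 0.13 (parental) and 0.11 (Fry clone) on the log2 scale, and the 2 arrays of a pair within a group shared identical values in at most 2.15% of probe sets. The labels give no batch or scan date, and no passage number for any sample. The fit was tested on simulated data made from the means and spread of this comparison, with 200 of 32768 probe sets changed. It recovered 98% of changes of 1 and 100% of changes of 2 on the log2 scale. Recovery was not split by signal level, so these values do not show how many changes of dim probe sets are found. Of its calls 8.33% were unchanged probe sets, a share above the 0.05 set for the adjusted p. In the data 20437 of 32768 probe sets passed, so the simulated setting held far fewer changes. A list shifted on purpose was called and 0 of 20 lists of unchanged probe sets were. The simulated noise was independent for each probe set, so genes did not move together. In the data the estimated correlation within a list reached 0.59, for interferon-induced genes, so the simulation does not check the calls of lists. The alternatives were pseudocounts of 1 and 64, no filter or a 60th percentile filter, quantile normalization, median centring, an intensity trend with a robust prior, array weights, a replicate block, leaving out probe sets of the _s_at and _x_at types, averaging the probe sets of a gene, stricter thresholds and leaving out each array in turn. Per the labels, all samples labelled Fry clone come from 1 selected clone, and no clone with an empty vector is described. The design does not separate effects of Fry from those of selection or of the clone. Nor does it separate them from a difference of cell line, which is examined below.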

Results

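Gene expression was measured on 6 one-colour Affymetrix arrays of total RNA labelled as from a human breast cancer cell line and a clone of it. MDA-MB-231 is an established line of invasive, mesenchymal-like breast tumour cells that lacks the oestrogen receptor. The parental group held 3 samples of untransfected cells. The other group held 3 samples labelled as 231wCFry, a stable clone of MDA-MB-231 that, per the labels, was transfected with a cDNA of 10791 base pairs encoding wild-type Fry of the Copenhagen rat. Fry is a large scaffold protein that binds NDR-family kinases. Per the labels the clone went through puromycin selection and was chosen for a Fry level near that of a normal mammary epithelial line, and no clone carrying an empty vector is described. The series' design text says that the samples of each line varied in passage number, without giving the passage of any sample. The labels name no separate cultures, so how far the spread between these samples is technical or reflects passage is not known. The p-values measure only that spread, not the spread between clones. The values were MAS5 signals in arbitrary units, with the same trimmed mean on every array. The number of arrays, 3 per group, limits the precision of every value.

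By its labels the comparison asks how introducing Fry alters the transcripts of these cells, so the targeted gene was read first. Human FRY was dim in both groups. Its 4 probe sets read at most 9.8 on any of the 6 arrays, below the median signal of all probe sets (10.4 to 12.1). The filter on low values removed all 4, so they were tested in a limma fit without the filter. The one with the highest mean over all 6 arrays stood at 5.83 ± 0.96 (SD, n = 3) in the parental samples and 3.97 ± 1.05 in the samples labelled Fry clone, a log2 difference of -0.13 that did not pass (adjusted p = 0.25). Another did not pass either (-0.12, adjusted p = 0.52). The remaining FRY probe sets fell to a level not above background in the samples labelled Fry clone, so their folds are lower bounds against the unspiked bacterial control probe sets. The first went from 8.27 ± 2.08 to 0.37 ± 0.25 (at least 2.29-fold lower, adjusted p = 9.72e-04) and the second from 6.3 ± 1.71 to 2.7 ± 0.50 (at least 1.75-fold lower, adjusted p = 0.040). The introduced cDNA is of rat, and where these human probes lie relative to it was not determined, so the readings do not check the presence of the transgene. FRYL, the human paralog of FRY, fell from 278 ± 13.5 to 107 ± 12.7 (log2 change -1.26, SE 0.10, adjusted p = 5.27e-06), and of its 4 other tested probe sets 3 fell and none rose.

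The samples labelled Fry clone differed from the parental samples in most genes tested. They may come from another cell line, as examined below, so no change in single genes or gene lists can be assigned to Fry. SOX10, a transcription factor of the neural crest, rose from 0.43 ± 0.32 to 1395 ± 22.3 (SD, n = 3) and S100B, a calcium-binding protein of melanocytes and glia, from 0.70 ± 0.87 to 1770.1 ± 93.3. KRT19, a keratin of simple epithelia, fell from 1669 ± 43.5 to 1.1 ± 0.35 and PLAU, the urokinase plasminogen activator, from 2579 ± 392 to 6.2 ± 0.92. Among 13606 genes tested, 4616 rose and 4483 fell at a Benjamini-Hochberg adjusted p under 0.05 (limma). At a log2 change of at least 1, 1666 rose and 1460 fell, and at least 3, 273 rose and 275 fell. Over probe sets, 20437 of 32768 passed, 9899 of them higher and 10538 lower. The groups did not overlap in 9927 genes (73%), where chance gives 10% for 3 samples against 3. Pearson's correlation across probe sets, which are not independent replicates, lay between 0.992 and 0.995 for the 6 pairs of arrays within a group and between 0.869 and 0.874 for the 9 pairs between groups. The first principal component, which separated the groups, held 93.5% of the variance. The 3'-to-5' signal ratio of the GAPDH control probe sets, a sign of RNA quality, also moved with the groups, at 1.36 to 1.39 on the parental arrays and 1.24 to 1.33 on the arrays labelled Fry clone.

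**Figure D1:**
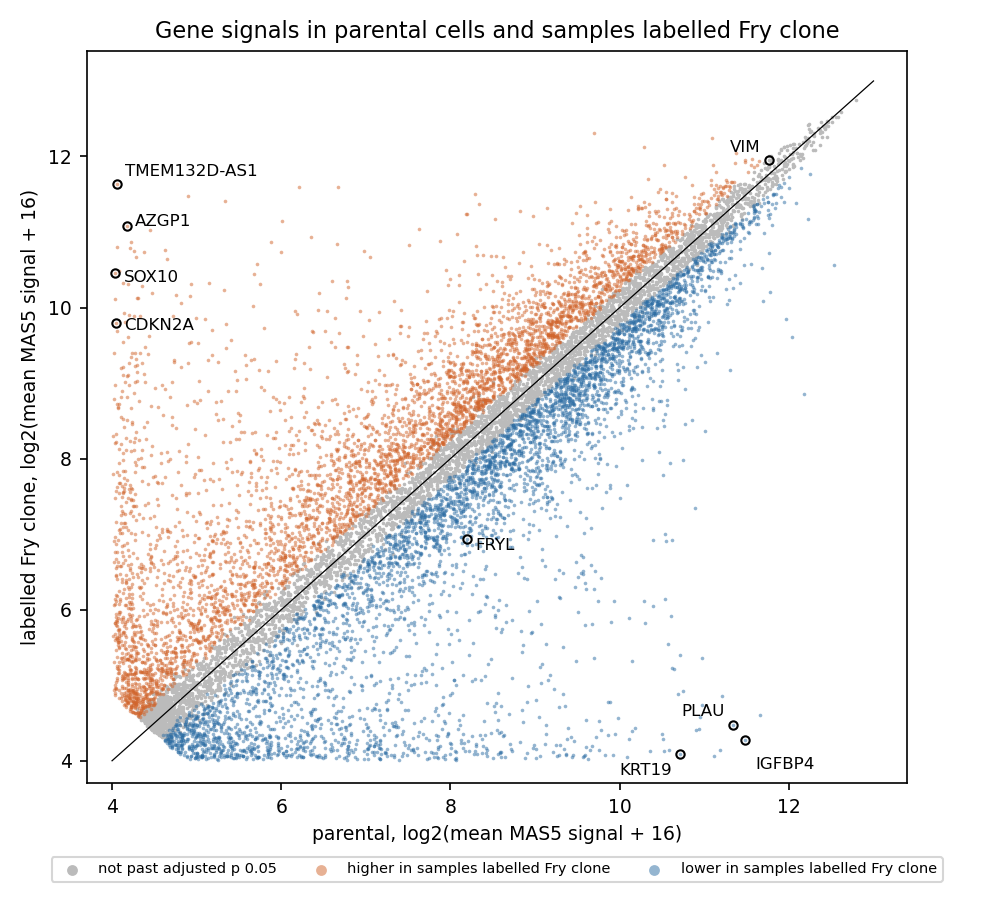
Mean MAS5 signal of each of 13606 genes in the 3 parental samples (x axis) and the 3 samples labelled Fry clone (y axis), as log2(mean signal + 16), with points coloured by direction where the limma adjusted p was under 0.05, open circles on named genes and a line marking equal signals. TMEM132D-AS1, AZGP1, SOX10 and CDKN2A lie at the left edge with high values in the samples labelled Fry clone, and IGFBP4, PLAU and KRT19 lie at the lower right.

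Rises and falls were ranked on log2(signal + 16), a scale on which genes at background in a group have no settled order. First among the rises on that scale was TMEM132D-AS1, an antisense transcript, which went from 0.67 ± 0.72 to 3173 ± 191 (SD, n = 3), with a log2 change of 7.58 (SE 0.09, adjusted p = 1.28e-10). The background level, set on each array at the highest signal of the unspiked bacterial control probe sets, lay below the median signal of all probe sets (10.4 to 12.1). Folds given as at least a value are bounds against this level, and a higher floor would make them smaller. Against it TMEM132D-AS1 was at least 925-fold higher. On the same basis AZGP1, a secreted zinc-binding glycoprotein, was at least 629-fold higher, S100B at least 516-fold, CNRIP1, a protein that binds cannabinoid receptors, at least 512-fold, HLA-DQA1, a class II histocompatibility gene, at least 414-fold and SOX10 at least 407-fold. OVAAL, a long noncoding RNA, rose from 2.73 ± 2.01 to 1861 ± 143 and SCRG1 from 5.83 ± 2.69 to 2079 ± 123. SYTL5, a synaptotagmin-like protein, rose from 3.2 ± 2.61 to 1702 ± 75 and CD109, a surface glycoprotein, from 3.47 ± 2.42 to 1609.8 ± 42.6. MAGEA6 rose from 13.7 ± 4.21 to 2844 ± 268 and HLA-DQB1 from 4.77 ± 1.01 to 1693 ± 44.8, both read by probe sets of a type prone to cross-hybridise with close paralogs, so which paralog they read is uncertain. The adjusted p of these 12 rises was at most 3.81e-10.

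First among the falls on that scale was IGFBP4, a secreted binder of insulin-like growth factors, which went from 2851 ± 164 to 3.37 ± 0.85 (log2 change -7.21, SE 0.09, adjusted p = 1.28e-10). PRDX1, a peroxiredoxin, fell from 3221 ± 166 to 8.4 ± 1.39 on the only probe set tested for it. Against the same background level, CYP1B1, a cytochrome P450, was at least 652-fold lower, C19orf33 at least 625-fold, KRT19 at least 474-fold, MBP, whose locus encodes myelin basic protein, at least 429-fold, and C4BPB, a chain of the complement regulator C4b-binding protein, at least 413-fold. PLAC8 fell from 1952 ± 181 to 5.33 ± 1.64, EDIL3, a matrix protein that binds integrins, from 1900.1 ± 283 to 5.27 ± 2.54, and the zinc finger gene ZNF22 from 1958 ± 41 to 7.8 ± 2.4. SPANXB1, of a sperm protein family, fell from 2347 ± 212 to 12.9 ± 1.7. The adjusted p of these 12 falls was at most 5.59e-10. Where these 24 genes had other tested probe sets, those passed in the same direction.

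**Figure D2:**
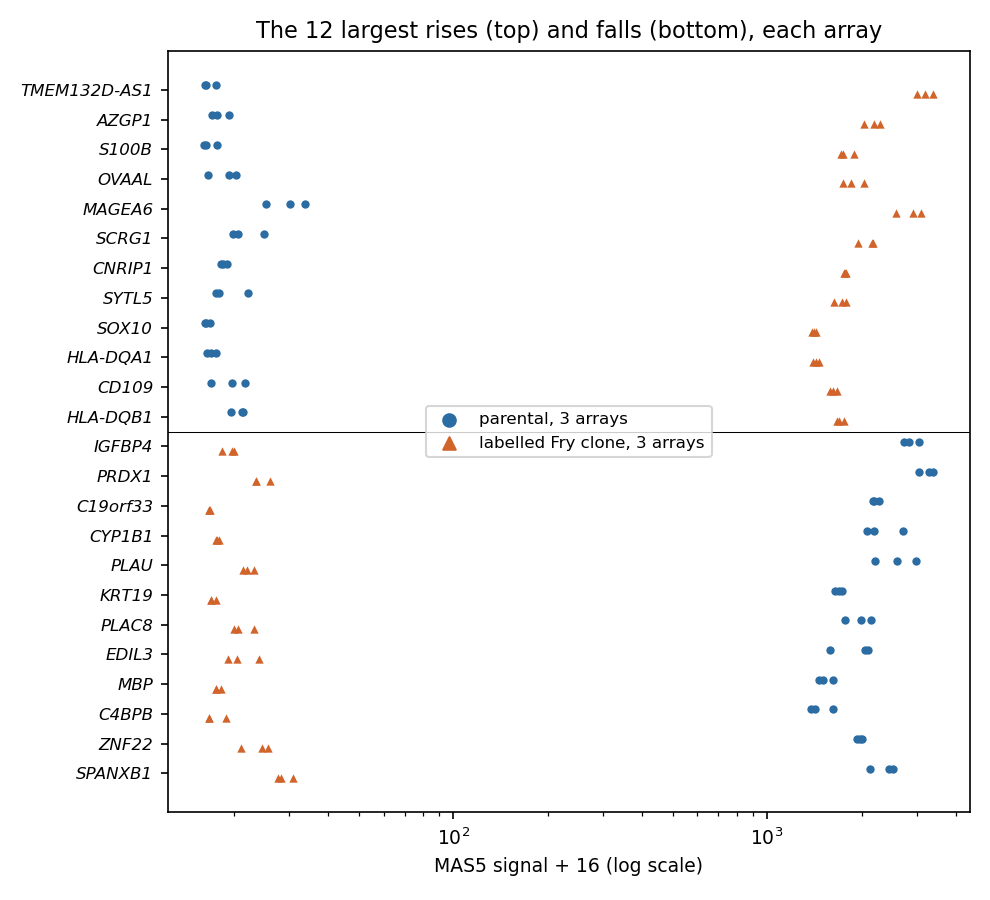
MAS5 signal plus 16 on a log scale (x axis) on each of the 3 parental arrays (circles) and the 3 arrays labelled Fry clone (triangles) for the 12 genes with the largest rise and the 12 with the largest fall on log2(signal + 16). The groups of 3 points are separated in every gene.

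More genes of epithelial identity fell than rose in the samples labelled Fry clone. Of 24 tested epithelial genes, 1 rose, 17 fell and 6 did not pass, and adjusted over the list alone 1 rose and 18 fell, with a median log2 change of -1.31 (camera adjusted p = 8.70e-06, and adjusted p = 0.10 with an estimated correlation). Besides KRT19, the protease inhibitor SPINT2 fell from 1092 ± 61.5 to 3.5 ± 2.0 (SD, n = 3), the keratin KRT8 from 1543 ± 219 to 44.7 ± 3.28 and the adhesion molecule EPCAM from 234 ± 31.7 to 4.6 ± 2.29. Of 27 tested mesenchymal genes, 10 rose, 13 fell and 4 did not pass, and adjusted over the list alone 10 rose and 13 fell (camera adjusted p = 0.60, and adjusted p = 0.74 with an estimated correlation). TWIST1, a transcription factor of mesenchymal cells, rose from 1.7 ± 0.72 to 960.2 ± 131 and the matrix protein SPARC from 48.4 ± 7.09 to 2249 ± 37.9, while the cadherin CDH11 fell from 774 ± 21.1 to 0.23 ± 0.058 and the collagen cross-linking enzyme LOX from 826 ± 81.2 to 3.93 ± 0.74. Of 16 tested luminal breast genes, 5 rose, 7 fell and 4 did not pass, and adjusted over the list alone 5 rose and 7 fell (camera adjusted p = 0.50, and adjusted p = 0.74 with an estimated correlation), and the receptor ERBB3 rose from 20.2 ± 6.05 to 816 ± 55.8 and GREB1 from 9.27 ± 4.56 to 235 ± 7.9. Of 13 tested basal and myoepithelial breast genes, 4 rose, 7 fell and 2 did not pass, and adjusted over the list alone 4 rose and 7 fell (camera adjusted p = 0.44, and adjusted p = 0.64 with an estimated correlation). SFN, a 14-3-3 protein of epithelia, fell from 1467 ± 56.9 to 54.6 ± 4.1, the laminin chain LAMB3 from 863 ± 38.8 to 69.2 ± 15.9, and KRT14 rose from 1.03 ± 1.19 to 113 ± 4.83. For the genes named in these lists the adjusted p was at most 3.52e-08. In these samples SOX10 stood at 1395 ± 22.3, against 0.43 ± 0.32 in the parental samples, and the GAPDH 3'-to-5' ratio at 1.24 to 1.33, against 1.36 to 1.39.

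Among components of the NDR and Hippo kinase pathways, to which Fry is linked, and targets of the pathway effectors YAP and TAZ, more genes fell than rose. These counts do not show an effect of Fry, since the groups may be of different cell lines. Of 25 tested pathway components, 5 rose, 14 fell and 6 did not pass, and adjusted over the list alone 5 rose and 15 fell (camera adjusted p = 0.072, and adjusted p = 0.49 with an estimated correlation). WWC1, an upstream regulator of the pathway, fell from 1140.3 ± 48.9 to 5.67 ± 0.91 (SD, n = 3) and the NDR kinase STK38 from 2103 ± 131 to 879.9 ± 60.7, while the tumour suppressor NF2 rose from 167 ± 1.77 to 1806 ± 117 and the transcription factor TEAD4 from 346 ± 22.9 to 1173 ± 95.1. Of 21 tested YAP and TAZ targets, 1 rose, 14 fell and 6 did not pass, and adjusted over the list alone 1 rose and 14 fell, with a median log2 change of -0.70 (camera adjusted p = 0.0029, and adjusted p = 0.49 with an estimated correlation). IGFBP3, a secreted binder of insulin-like growth factors, fell from 593 ± 62.8 to 2.43 ± 1.62, ANKRD1 from 289 ± 77.3 to 4.03 ± 2.74, CCDC80 from 452 ± 76.8 to 69.5 ± 7.46 and NT5E, the ectoenzyme CD73, from 3297 ± 95.6 to 1067 ± 50.5. Each of these named genes passed with an adjusted p of at most 3.51e-06. In these samples SOX10 stood at 1395 and S100B at 1770.1, against 0.43 and 0.70 in the parental samples, and the GAPDH 3'-to-5' ratio at 1.24 to 1.33, against 1.36 to 1.39.

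Among mitosis genes more fell than rose. Of 40 tested mitosis and G2/M genes, 4 rose, 24 fell and 12 did not pass, and adjusted over the list alone 4 rose and 24 fell, with a median log2 change of -0.34 (camera adjusted p = 0.017, and adjusted p = 0.64 with an estimated correlation). MKI67, which encodes the proliferation marker Ki-67, fell from 512 ± 4.98 to 243 ± 24.8 (SD, n = 3), the kinetochore motor CENPE from 467 ± 56.1 to 215 ± 2.1 and DLGAP5 from 1575 ± 84 to 774 ± 71.3, while HMMR, a hyaluronan receptor that also acts at the spindle, rose from 305 ± 31.1 to 1378 ± 57.1. Of 41 tested DNA replication and S-phase genes, 8 rose, 16 fell and 17 did not pass, and adjusted over the list alone 8 rose and 16 fell (camera adjusted p = 0.44, and adjusted p = 0.74 with an estimated correlation). The replication factor GINS3 rose from 814 ± 31.6 to 1749 ± 74.2 and the polymerase subunit POLE2 fell from 1038 ± 41.1 to 519 ± 40.6. Of 25 tested p53 targets, 5 rose, 13 fell and 7 did not pass, and adjusted over the list alone 7 rose and 13 fell (camera adjusted p = 0.27, and adjusted p = 0.49 with an estimated correlation). SESN2 rose from 38.1 ± 8.3 to 263 ± 21.8 and the kinase PLK2 fell from 1021 ± 53.3 to 379 ± 20.2. Of 23 tested EGF-family ligands, receptors and regulators, 6 rose, 12 fell and 5 did not pass, and adjusted over the list alone 6 rose and 13 fell (camera adjusted p = 0.072, and adjusted p = 0.49 with an estimated correlation). The ligand TGFA fell from 801 ± 44.8 to 40.2 ± 1.12, NRG1 from 328 ± 40 to 1.73 ± 1.36 and EREG from 303 ± 59.8 to 1.0 ± 0.82. The genes named here had an adjusted p of at most 1.94e-05. In these samples SOX10 stood at 1395, against 0.43 in the parental samples, and CDKN2A, an inhibitor of cyclin-dependent kinases chosen after its values were seen, was at least 255-fold higher. The GAPDH 3'-to-5' ratio was 1.24 to 1.33 in them, against 1.36 to 1.39.

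Among genes of unfolded protein and amino-acid stress more rose than fell. Of 31 tested stress genes, 17 rose, 3 fell and 11 did not pass, and adjusted over the list alone 17 rose and 3 fell, with a median log2 change of 0.46 (camera adjusted p = 0.0097, and adjusted p = 0.49 with an estimated correlation). The secreted hormone STC2 rose from 9.03 ± 1.85 to 1590.2 ± 32.9 (SD, n = 3), PHGDH, the first enzyme of serine synthesis, from 38 ± 4.25 to 1258 ± 59, and TRIB3, a pseudokinase, from 93.3 ± 10.4 to 549 ± 40.7. Of 19 tested cholesterol synthesis genes, 2 rose, 12 fell and 5 did not pass, and adjusted over the list alone 2 rose and 12 fell, with a median of -0.42 (camera adjusted p = 0.034, and adjusted p = 0.49 with an estimated correlation). The sterol transport gene STARD4 fell from 447 ± 94.3 to 30.1 ± 2.99, ACAT2 from 1319 ± 40.9 to 428 ± 12.8 and INSIG1 from 905 ± 126 to 435 ± 15.2. The call of the cholesterol list ended when probe sets of types prone to cross-hybridise were left out (camera adjusted p = 0.17). Of 34 tested hypoxia and glycolysis genes, 13 rose, 10 fell and 11 did not pass, and adjusted over the list alone 13 rose and 10 fell (camera adjusted p = 0.75, and adjusted p = 0.78 with an estimated correlation). ENO2, a glycolytic enzyme, fell from 365 ± 49.8 to 53.7 ± 16 and ANGPTL4 from 216 ± 99.7 to 0.37 ± 0.058, and the kinase PDK1 rose from 299.7 ± 0.79 to 709 ± 47.5. For the genes named in these lists the adjusted p was at most 3.75e-05. In these samples SOX10 stood at 1395, against 0.43 in the parental samples, and the GAPDH 3'-to-5' ratio at 1.24 to 1.33, against 1.36 to 1.39.

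Among interferon-induced genes more fell than rose. Of 40 tested interferon-induced genes, 9 rose, 21 fell and 10 did not pass, and adjusted over the list alone 10 rose and 22 fell, with a median log2 change of -0.52 (camera adjusted p = 0.044, and adjusted p = 0.74 with an estimated correlation). IFI27 fell from 523 ± 90.9 to 16.5 ± 4.32 (SD, n = 3), SAMD9 from 537 ± 28.4 to 79.8 ± 9.04 and the antiviral membrane protein IFITM2 from 1536 ± 146 to 229 ± 25.5. The call of this list was lost without the second parental array (camera adjusted p = 0.054), without the third array labelled Fry clone (0.077), with a 60th percentile filter (0.063), with quantile normalization (0.0503) and without probe sets of types prone to cross-hybridise (0.24). Of 25 tested cytokine and inflammatory genes, 8 rose, 8 fell and 9 did not pass, and adjusted over the list alone 8 rose and 8 fell (camera adjusted p = 0.76, and adjusted p = 0.79 with an estimated correlation). The cytokine IL11 fell from 814 ± 112 to 25 ± 6.1 and IL6 from 267 ± 27.9 to 8.3 ± 2.71, and the chemokine CCL2 rose from 12.1 ± 4.66 to 578 ± 72.2. Of 29 tested TGF-beta-induced genes, 8 rose, 15 fell and 6 did not pass, and adjusted over the list alone 8 rose and 15 fell (camera adjusted p = 0.24, and adjusted p = 0.59 with an estimated correlation). The co-receptor ENG rose from 10.1 ± 3.67 to 359 ± 38.5 and the latent TGF-beta binding protein LTBP2 fell from 268 ± 36.9 to 19.2 ± 4.62. Of 10 tested leukocyte markers, 2 rose, 3 fell and 5 did not pass, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.78, and adjusted p = 0.79 with an estimated correlation). LCP2, a signalling adaptor of leukocytes, rose from 0.90 ± 0.61 to 37.6 ± 2.67, and CD8A, a T-cell coreceptor, fell from 56.8 ± 13.8 to 1.97 ± 0.70. Each of these named genes passed with an adjusted p of at most 1.20e-06. In these samples S100B stood at 1770.1, against 0.70 in the parental samples, and the GAPDH 3'-to-5' ratio at 1.24 to 1.33, against 1.36 to 1.39.

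Matrix and adhesion genes changed in both directions. Of 28 tested matrix proteases and inhibitors, 8 rose, 13 fell and 7 did not pass, and adjusted over the list alone 8 rose and 13 fell (camera adjusted p = 0.44, and adjusted p = 0.64 with an estimated correlation). The stromelysin MMP3 rose from 4.9 ± 0.90 to 695 ± 24 (SD, n = 3) and the metalloprotease ADAMTS1 from 22.2 ± 0.96 to 349.7 ± 11.6, and ADAM8 fell from 382 ± 6.21 to 4.2 ± 2.35. The median of this list was -0.23 and camera's direction was down, while limma's rotation test, named fry, gave up without passing (adjusted p = 0.73). Of 18 tested integrins, 7 rose, 6 fell and 5 did not pass, and adjusted over the list alone 7 rose and 6 fell (camera adjusted p = 0.78, and adjusted p = 0.79 with an estimated correlation). ITGA4 rose from 16.8 ± 1.2 to 424 ± 21.5 and ITGB8 from 7.2 ± 1.37 to 191 ± 5.04, and ITGB4 fell from 203 ± 15.9 to 22.9 ± 2.8 and ITGA3 from 839.7 ± 21 to 230.2 ± 9.27. Of 34 tested genes known to vary between metastatic sublines of MDA-MB-231, 9 rose, 21 fell and 4 did not pass, and adjusted over the list alone 9 rose and 21 fell, with a median of -0.98 (camera adjusted p = 0.072, and adjusted p = 0.49 with an estimated correlation). The chemokine receptor CXCR4 fell from 634 ± 34.6 to 1.87 ± 0.40, and SPP1, which encodes osteopontin, rose from 3.63 ± 1.88 to 1106 ± 125. Without the second parental array the subline list passed (camera adjusted p = 0.041). The genes named here had an adjusted p of at most 1.23e-07. In these samples SOX10 stood at 1395 and S100B at 1770.1, against 0.43 and 0.70 in the parental samples, and the GAPDH 3'-to-5' ratio at 1.24 to 1.33, against 1.36 to 1.39.

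Among cancer-testis antigen genes, normally confined to germ cells and active in some tumours, more rose than fell. The list held 29 genes, of which 11 were tested. Genes silent in both groups fail the filter on low values, so the counts and the median leave such genes out. Of 11 tested cancer-testis genes, 9 rose, 2 fell and 0 did not pass, and adjusted over the list alone 9 rose and 2 fell, with a median log2 change of 4.84 (camera adjusted p = 8.15e-04, and adjusted p = 0.15 with an estimated correlation). MAGEA12 was at least 319-fold higher, CTAG2 rose from 1.47 ± 1.27 to 1269.9 ± 24.8 (SD, n = 3) and MAGEC2 from 6.23 ± 0.49 to 1149 ± 105, while SPANXB1 fell from 2347 ± 212 to 12.9 ± 1.7. The adjusted p of these genes was at most 2.38e-10. Without probe sets of types prone to cross-hybridise the call of this list was lost (camera adjusted p = 0.24). In these samples SOX10 stood at 1395, against 0.43 in the parental samples, and the GAPDH 3'-to-5' ratio at 1.24 to 1.33, against 1.36 to 1.39. Of the 21 lists, 7 passed by camera with a preset correlation, 5 lower and 2 higher, and 10 had an unadjusted p under 0.05. None passed by camera with the correlation estimated from the data, where 2 had an unadjusted p under 0.05. For the epithelial and cancer-testis lists the estimated correlation was -0.018 and -0.002, below the preset 0.01. A higher correlation between genes therefore does not account for the loss of their calls. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 20.

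**Figure D3:**
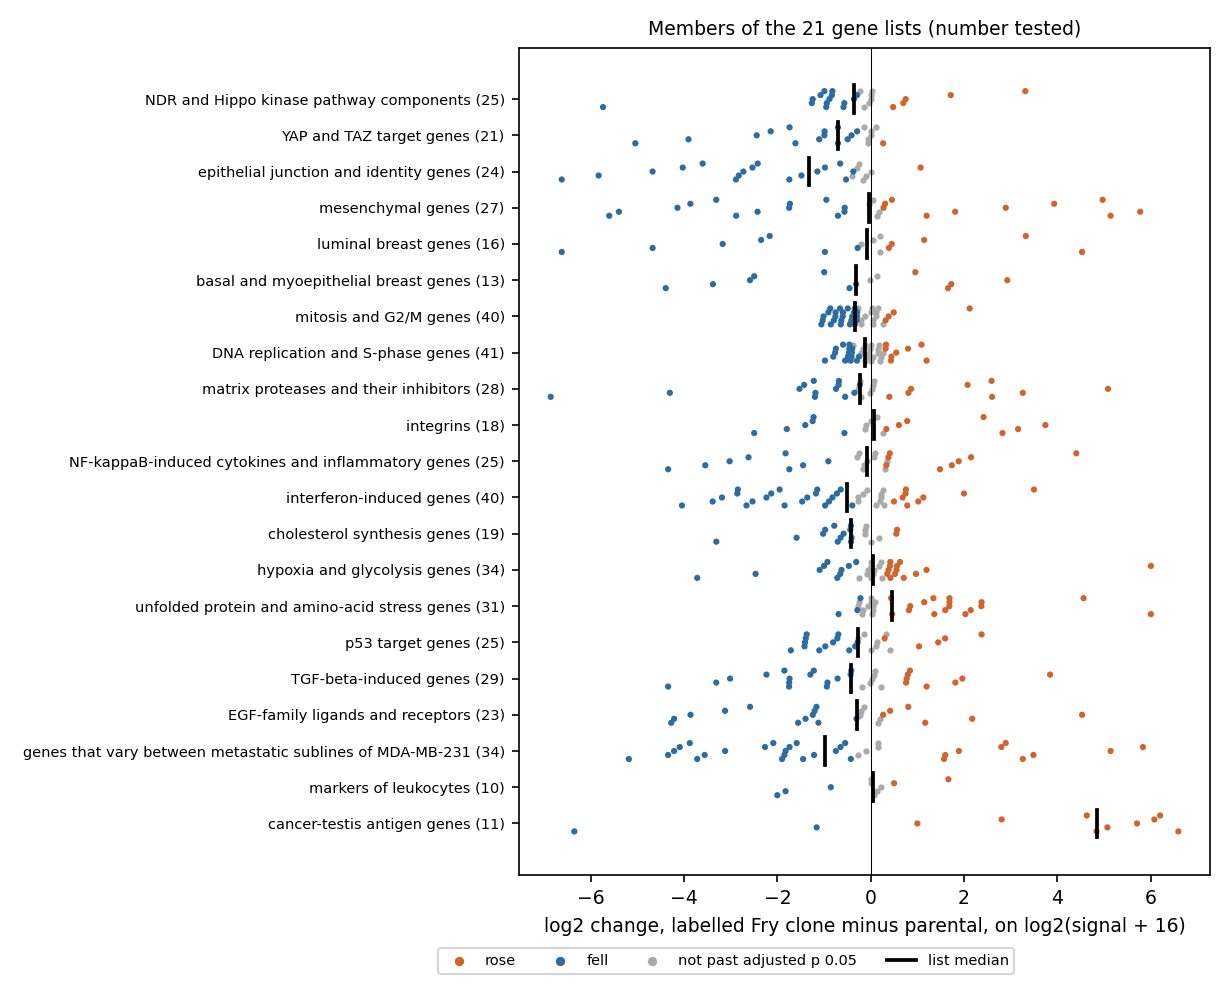
Log2 change (samples labelled Fry clone minus parental, on log2(signal + 16), x axis) of each tested member of the 21 gene lists (y axis, number tested in parentheses), coloured by direction where the limma adjusted p was under 0.05 and grey otherwise, with the list median as a bar. Each list held members that rose and members that fell, and the median was lowest for epithelial genes (-1.31) and highest for cancer-testis antigens (4.84).

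Neighbouring genes on chromosome 9 and a further list of melanocyte and neural crest genes were chosen after the leading genes had been seen. FOCAD, KLHL9, MTAP, CDKN2A, CDKN2B and ELAVL2 read at most 7.5 on every parental array over all their probe sets. In the samples labelled Fry clone MTAP, an enzyme of methionine salvage, read 537 ± 12.7 (SD, n = 3) and CDKN2A 874 ± 56.3. FOCAD read 212 ± 6.53, KLHL9 304 ± 13, CDKN2B 207 ± 21.1 and ELAVL2 299 ± 4.05, and the adjusted p of the 6 genes was at most 5.02e-09. The other genes measured between FOCAD and ELAVL2, among them interferon alpha genes, read at most 10 on each of the 6 arrays. The genes flanking this stretch were present in the parental samples, MLLT3 at 143 ± 8.4 and TUSC1 at 584 ± 39.6, and TUSC1 fell to 14.9 ± 2.36 in the samples labelled Fry clone. A list of 27 melanocyte and neural crest genes whose values had not been looked at had 24 on the array. The filter on low values left 18, of which 17 rose and 0 fell. A gene silent in the parental samples passes that filter only through its signal in the other group, which favours rises. Some that rose stayed dim in the samples labelled Fry clone, among them TYR at 25.5 ± 8.61 and MLANA at 35.5 ± 25.2. The calcium-binding protein S100A1 rose from 10.4 ± 6.32 to 931 ± 119, the melanosomal receptor GPR143 from 8.17 ± 1.61 to 486 ± 29.8 and MITF, a regulator of the melanocyte lineage, from 399 ± 39.8 to 1129 ± 65.3. PMEL, a melanosome protein, did not pass, at 10.8 ± 5.63 in the parental samples and 5.17 ± 2.67 in the others.

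**Figure D4:**
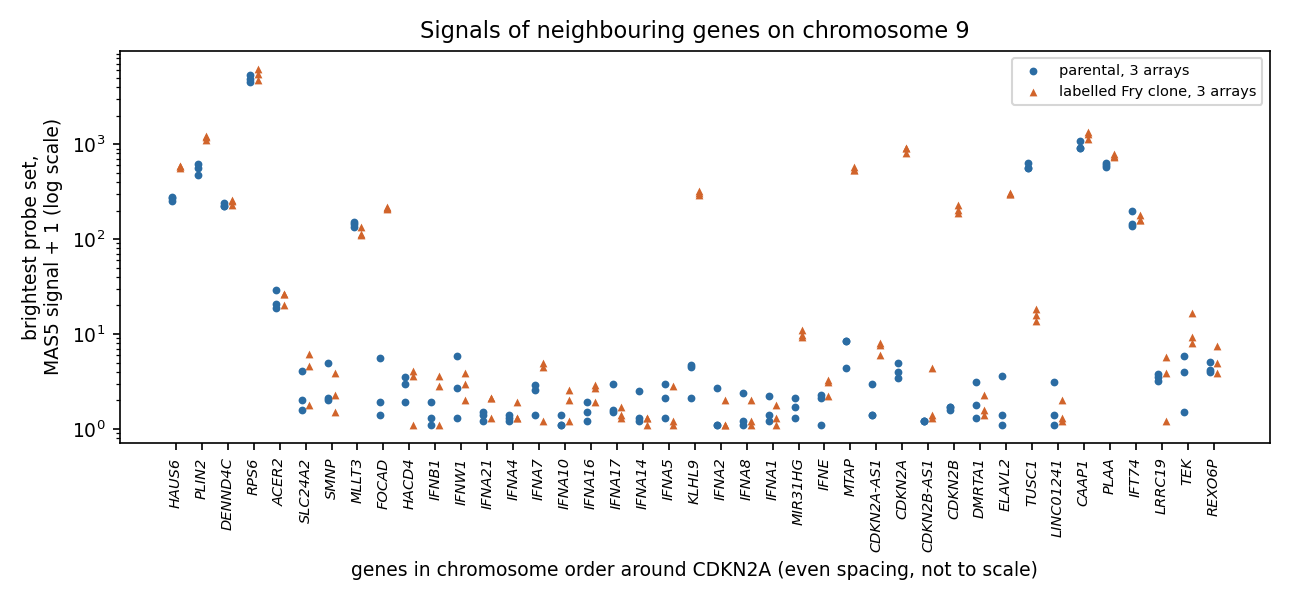
Signal of the brightest probe set of each gene plus 1 (y axis, log scale) for neighbouring genes in chromosome order around CDKN2A (x axis, evenly spaced) on the 3 parental arrays (circles) and the 3 arrays labelled Fry clone (triangles). FOCAD, KLHL9, MTAP, CDKN2A, CDKN2B and ELAVL2 lie near the floor on the parental arrays alone, and MLLT3 and TUSC1 on either side are present there.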

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

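The comparison of control probe sets was set up after the data had been examined. Tests of outlying samples were not made, since the groups hold 3 samples each, and there is a single contrast. The control probe sets for human RNA are outside the comparisons above. In 2 of 13 such probe sets every array labelled Fry clone read above every parental array, where chance gives 5% of probe sets. The reverse direction was not counted. Among the tested genes the groups did not overlap in 73%, over both directions, so these 2 probe sets do not stand out in this series. The 3' control for 18S ribosomal RNA read 350.9 ± 38.2 in the samples labelled Fry clone and 214 ± 29.8 in the parental samples (SD, n = 3). A 5' control for 28S ribosomal RNA read 37.0 ± 0.66 in the samples labelled Fry clone and 30.2 ± 5.26 in the parental samples (SD, n = 3).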

How the results depend on the processing

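The alternatives were fixed before the data were examined, with 2 exceptions chosen after seeing the data. The limit to genes with a mean signal of at least 100 in a group called 6637 genes. The bounds of 60 and 200 are used below for lineage genes and runs of neighbouring genes. The count of changed genes stayed within 1.5 times the reported 9099 in 12 of 13 alternatives and that of probe sets in 10 of 12. With a log2 change of at least 1 required, 6170 probe sets (3235 higher, 2935 lower) and 3126 genes (1666 higher, 1460 lower) passed. Without _s_at and _x_at probe sets fewer were tested, and 13016 passed (6342 higher, 6674 lower) with 4 lists. Camera with an estimated correlation called 0 lists and fry 20. Leaving out each array in turn gave 18648 to 19612 probe sets, 8950 to 9704 higher and 9505 to 9929 lower, 8360 to 8809 genes, 4173 to 4514 higher and 4094 to 4295 lower, 6 to 7 lists, and a FRY difference of -0.17 to -0.09. The FRY probe set with the highest mean over all arrays did not pass with an array left out (adjusted p 0.20 to 0.49) or in the 8 other alternatives run for it (-0.47 to -0.04, adjusted p 0.16 to 0.42). The 60th percentile filter, which removes it, gave no value, and it was not tested with _s_at and _x_at probe sets left out. Deviations of same-numbered arrays correlated at 0.07, 0.07 and 0.19, and the highest with another number were 0.08, 0.08 and -0.07. Since not every pair exceeded 0.1, the numbers were not taken to pair the samples, although the arrays numbered 3 correlated best with each other and stood apart in both groups, with 31 and 34 values at 0 against 91 to 197 on the other arrays. With the replicate block 20770 probe sets and 9162 genes passed. Without the filter the lists of NDR and Hippo components, of EGF-family genes and of subline genes passed (camera adjusted p = 0.046 each). The 98 named genes were mostly chosen from these same arrays for large changes or small p, so their repeats do not show how stable other calls are. Of 1534 repeats over these genes, 1533 kept direction and side of the threshold. The exception was TAGLN without _s_at and _x_at probe sets (-0.06, adjusted p = 0.70), where another probe set represents it. Fewer probe sets tested, or a stricter threshold, give the lower counts above by construction. For the calls of lists the cause was not tested, beyond the estimated correlations given above. Signal over background limits FRY, whose probe sets are near the controls.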

Other observations

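The test of a mixture, the search for runs of genes silent in the parental samples, the bounds of 60 and 200, and the HLA and HOX lists were chosen after the values were seen. More antigen presentation genes of class II rose than fell in the samples labelled Fry clone. Of 15 class II genes and regulators, 12 rose and 2 fell, with a median log2 change of 3.02. HLA-DPB1 rose from 24.3 ± 11.8 to 2696 ± 61.9 (SD, n = 3), HLA-DRA from 298 ± 183 to 2895 ± 195 and CIITA, the transactivator of these genes, from 31 ± 15.3 to 312 ± 97.3. The parental arrays read HLA-DRA at 247, 501 and 145. Of 13 class I and peptide loading genes, 2 rose, 3 fell and 8 did not pass, and B2M read 4519 ± 262 in the parental samples and 4116 ± 343 in the others. HOX genes, which mark position along the body axis, also rose more often than they fell. Of 39 in the list 24 were tested, of which 20 rose and 2 fell. The filter on low values favours rises among genes silent in the parental samples here too. HOXC10 rose from 2.23 ± 1.76 to 762 ± 37.6 and HOXB7 from 19.2 ± 4.94 to 616 ± 50.6, and HOXD4 fell from 96.2 ± 14.5 to 6.5 ± 2.35. Some that rose stayed dim in the samples labelled Fry clone, among them HOXB13 at 10.6 ± 2.05 and HOXB8 at 25.5 ± 7.57.

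The lineage of the genes that rose was examined with lists of other tissues. All 5 melanocyte and neural crest genes seen before the test (SOX10, S100B, MIA, PAX3, GPM6B) were at most 30 on every parental array and at least 100 on every array labelled Fry clone. Of 24 further genes of that lineage on the array, 5 met the same bounds, 20.8%, namely CDH19, S100A1, GPR143, BCAN and GAS7. Among 8 other lineages the highest share was 10% (1 of 10 prostate genes, TRPM8), and the hepatocyte, neuron, skeletal muscle, adipocyte, endothelial, intestinal and keratinocyte lists had none (of 12 to 17 genes each). With bounds of 60 and 200 the share was 16.7% against 10% for prostate and 5.88% for neuron genes. Of these 24 further melanocyte and neural crest genes 18 passed the filter on low values, which favours rises among genes silent in the parental samples. In the limma test 17 of the 18 rose and 0 fell. Of the other lineages the same test gave 1 risen and 3 fallen of 6 hepatocyte genes, 4 risen and 0 fallen of 8 neuron genes, 2 risen and 2 fallen of 6 skeletal muscle genes, 1 risen and 3 fallen of 5 adipocyte genes, 1 risen and 5 fallen of 7 endothelial genes, 1 risen and 1 fallen of 2 intestinal epithelium genes, 2 risen and 2 fallen of 5 prostate epithelium genes, 0 risen and 1 fallen of 3 keratinocyte genes. Of the 24 further melanocyte and neural crest genes, 5 were at least 100 on every parental array, among them MITF and MCAM (means of 399 and 686), and 0 are also in another list here.

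A candidate explanation for the breadth of the difference is that the samples labelled Fry clone come from another cell line, with melanocyte or neural crest features, and not from MDA-MB-231, which is known to lack CDKN2A and its neighbour MTAP by deletion. CDKN2A had been seen to differ before the prediction for MTAP was written, so the readings of these neighbours are not independent. As predicted for another cell line before MTAP was read, MTAP stood at most at 7.5 on the parental arrays. It stood at least at 529 on the arrays labelled Fry clone, a log2 change of 4.98. This argues against a new state of the same genome through Fry, passage or selection, since a lost segment cannot be regained, provided that the parental silence is a deletion, which no DNA measurement here tests. A mixture with parental cells at a share of 5% or more is argued against by 24 of 3142 abundant parental probe sets (mean of at least 1000) that stayed under 1% of the lowest parental array on every array labelled Fry clone, where a first bound of 50 such probe sets had been replaced by 10 after the count was seen. It stays open which line these cells would be, whether a culture or a label was exchanged, whether part of the parental stock never carried the loss, whether a smaller share of parental cells is present, and what Fry itself changed.

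Genes silent in the parental samples alone were compared with shuffled gene order, as a test of a chromosome segment lost from the parental cells and not from the samples labelled Fry clone. With 19690 genes in chromosome order, the longest run of genes at most 30 on every parental array and at least 100 on every array labelled Fry clone, not interrupted by a gene present in the parental samples, held 6 genes, against at most 4 in 1000 shuffles of gene order. These were the 6 genes from FOCAD to ELAVL2, in a test chosen after these genes had been seen. The next run, of 4, was in the HOXC cluster (HOXC13, HOTAIR, HOXC11 and HOXC10), as long as the longest in the shuffles, and HLA-DQA1 with HLA-DQB1 and DLX1 with DLX2 formed pairs. Neighbours of such clusters are regulated together, which shuffled gene order leaves out, so the longer run by itself does not separate a loss from shared regulation. With bounds of 60 and 200 the run held 5, against at most 4. In the opposite direction, predicted before it was run, the longest run held 3, within the shuffles (95th percentile 3), so the test neither shows nor excludes a chromosome segment lost from the samples labelled Fry clone and not from the parental cells.

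Such a run of 3 joined PRDX1 with its neighbours CCDC163 and MMACHC, the gene of a vitamin B12 processing protein. CCDC163 fell from 182 ± 26.6 to 4.8 ± 1.81 (SD, n = 3), MMACHC from 179 ± 16 to 2.03 ± 0.70 and PRDX1 from 3221 ± 166 to 8.4 ± 1.39. The others joined LRRC61 and RARRES2 with a pseudogene, and the cystatin genes CST4, CST1 and CST2.

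Grouping by chance was examined with all 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05. The real split called 20437 probe sets, 9099 genes and 7 lists, and in each case 1 of the 10 splits, the real one, reached that count. The highest of the other splits called 0 probe sets and 0 genes by limma (291 and 93 at an unadjusted p under 0.05). By camera the highest called 5 lists (7 at an unadjusted p under 0.05), and these highest values did not all come from the same split. Each other split put arrays of both groups on both sides, so the difference between the groups entered the spread. The absence of limma calls there follows from the design and does not measure chance.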
